A study of Homo sapiens with 9 samples.

How the data were processed

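RNA was measured on Affymetrix human gene arrays in H1 cells, an established line of human embryonic stem cells, supplied per the labels by Cellular Dynamics International. The 9 arrays fall into 3 groups of 3. Total RNA is the input, the ELAVL1 RIP is RNA brought down from lysate with an antibody against the RNA-binding protein ELAVL1, and the T7 control RIP is RNA brought down with an antibody against a bacteriophage coat protein, which serves as the negative control. Per the labels' protocols, the antibodies were bound to magnetic beads, incubated overnight with lysate and washed before the RNA was extracted and labelled by the Nugen pico method. The design text calls the 3 arrays of a group separate RIP runs, so the spread between arrays is that between runs. Groups and replicate numbers were taken from the sample titles. No 2 arrays held identical values.

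The deposited value table holds log2 values for 28869 probe sets on each array. PLIER, which summarises the probes of a probe set, is named in the submitters' processing notes without a version. Background correction, scaling between arrays and filters are not given in the sources used here. The lowest value on every array lay just above 4, the log2 of 16, and the array medians and standard deviations differed, so these probe set values were not themselves quantile normalized. Whether probe signals were normalized before they were summarised is not known here. Array values carry no read depth, and the number of arrays limits the precision. The authors also deposited 3 region lists, each attached to 1 array and each in 2 versions, with positions on human genome build hg19 according to the names of the lists. Each region in the lists deposited by the authors corresponds to a probe set and carries a score that falls linearly with its p-value, a value, a p-value and a q-value. In the lists attached to an ELAVL1 array and to a total RNA array, the deposited value is at least 2. What this value measures is not given in the sources used here, and it is not read here as a fold. In the list attached to a T7 control array, the deposited value is a linear signal. The second version of each deposited list holds the same positions, scores and values, with p and q written as −log10. The authors' statistical test is not given in the sources used here. The region values, scores, p-values and q-values are the authors' and were used only within a list.

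Gene names came from the platform annotation of the probe sets. It gave 1 gene symbol for 19310 probe sets, several for 1752 and none for 7807. Of the probe sets with 1 symbol, 19279 matched a RefSeq table of assembly GRCh38.p14 through their Entrez number and 0 symbols changed. That table was used for names and for the chromosome of each gene. In a comparison made after the results were seen, where the deposited regions of the authors gave the chromosome of the probe set standing for a gene, 2 of 77 respiratory chain genes, SDHC and SDHD, and 0 of the ribosomal protein genes lay on another chromosome, with no position for 29 of the 77, 50 of 64 cytosolic and 6 of 73 mitochondrial ribosomal protein genes. Probe sets with several symbols were tested but are not named. The 18377 genes with at least 1 such probe set were each represented by the probe set with the highest mean over the 9 arrays.

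Group means of the deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) over all 9 arrays at once, with no covariate, and the 3 group differences were tested with a two-sided test. The fit assumes for each probe set a spread shared by the 3 groups, which the unequal array correlations given below go against. P-values were adjusted by Benjamini-Hochberg over all probe sets within a comparison, and an adjusted p under 0.05 was called. No filter on dim probe sets was used. Gene lists were tested with camera from limma at its preset correlation of 0.01 and again with an estimated correlation, adjusted over 25 lists and 3 comparisons, which made 75 tests. A list of mitochondrially encoded RNAs had 0 measured members. Region overlap was counted with bedtools 2.31.1 at a minimum of 1 bp, in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

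The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, per comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 difference among called probe sets with 1 symbol whose arrays did not overlap between the groups, up to 2 members of each list with the smallest adjusted p, and always ELAVL1, ACTB and GAPDH. Alternatives were quantile normalization, median centring of each array, a variance trend with robust estimation, leaving out the third of probe sets with the lowest means (33.3%), only probe sets with 1 symbol, a log2(2^value + 16) scale, only the 6 arrays compared, the replicate number as a block, the mean over a gene's probe sets, an estimated correlation, and leaving out each array. Leaving out total RNA replicate 3 and T7 control replicate 1 together, and median centring of single genes, were added after the data were seen. When an array was left out, its group was assumed to vary like the others. A planned analysis of 3' UTR sequence was not run, because no genome or annotation of the build was used here.

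The fit was tested on simulated data in which 100 of 28869 probe sets were changed by 2 and 100 by 4 on the log2 scale. For ELAVL1 RIP against T7 control RIP it recovered 13 of the smaller and 82 of the larger changes, with 3 false calls among 28669 unchanged probe sets. For ELAVL1 RIP against total RNA it recovered 12 and 89, with 6 false calls. For the T7 control RIP against total RNA it recovered 9 and 94, with 14 false calls. The simulated arrays were drawn independently with the same spread in each group, unlike the real ones. The false calls therefore do not give the error rate in the real data.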

Results

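ELAVL1, also called HuR, is a ubiquitous protein that binds U-rich and AU-rich stretches of mRNA. RNA associated with it in H1 human embryonic stem cells was recovered by immunoprecipitation of the protein (RIP) and measured on 3 arrays. Each array reported 28869 probe sets as log2 levels. Total input RNA and RNA recovered with an antibody against a bacteriophage coat protein (T7 control RIP) were measured on 3 arrays each. The array medians were 6.94, 6.83 and 6.36 for total RNA replicates 1, 2 and 3, 6.83, 6.58 and 6.78 for the T7 control RIP, and 6.37, 6.43 and 6.49 for the ELAVL1 RIP.

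The ELAVL1 arrays resembled each other closely, with Pearson correlations from 0.944 to 0.963 across probe sets, which are not independent replicates. Total RNA replicates 1 and 2 correlated at 0.979, but replicate 3 correlated with them at only 0.628 and 0.660, and at 0.835 and 0.820 with T7 control replicates 2 and 3. T7 control replicates 2 and 3 correlated at 0.960, and replicate 1 correlated with them at 0.516 and 0.517, and at 0.752 and 0.751 with total RNA replicates 1 and 2. Histone genes were among the lists that showed the split. The median of 54 replication-dependent histone genes was 6.32, 6.32 and 10.10 on the total RNA arrays, 5.56, 7.91 and 8.16 on the T7 control arrays and 5.99, 5.98 and 6.22 on the ELAVL1 arrays. The median of 32 pluripotency genes was 7.83, 7.90 and 9.31 in total RNA, 7.54, 9.66 and 9.98 in the T7 control RIP and 8.71, 8.95 and 8.83 in the ELAVL1 RIP. Each comparison with a control is therefore also given without total RNA replicate 3 and T7 control replicate 1, a choice made after the data were seen. The total RNA arrays kept then have pluripotency medians of 7.83 and 7.90, below every ELAVL1 array and below the T7 control arrays kept. Results without both arrays thus cannot separate enrichment from a difference between the samples.

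**Figure D1:**
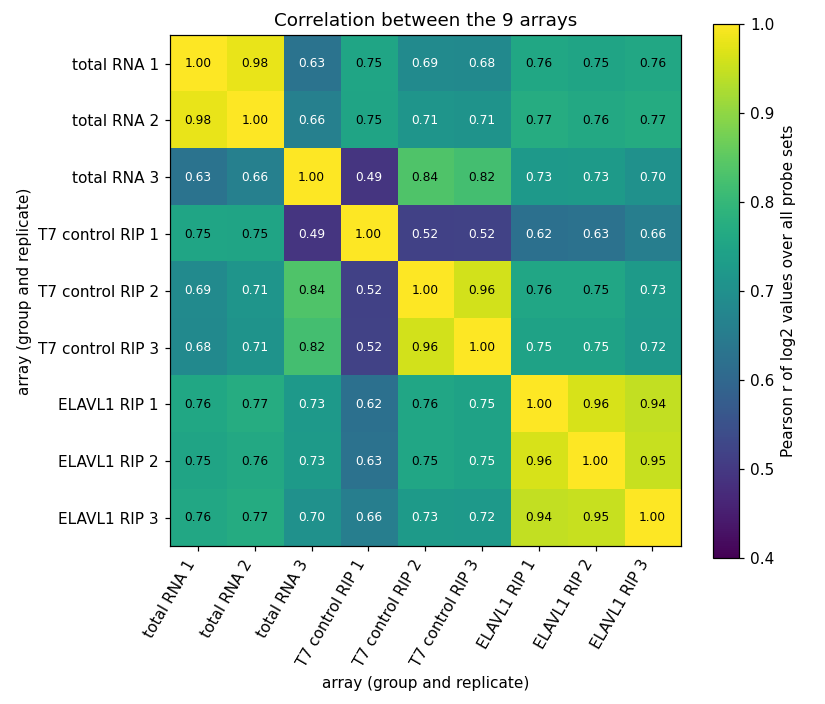
Pearson correlation of log2 values over all 28869 probe sets for each pair of the 9 arrays, with both axes listing the arrays by group and replicate and the colour giving r. The 3 ELAVL1 arrays correlate at 0.944 to 0.963, while total RNA replicate 3 correlates better with T7 control replicates 2 and 3 (0.835 and 0.820) than with total RNA replicates 1 and 2 (0.628 and 0.660).

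The comparison of ELAVL1 RIP with T7 control RIP asks which RNAs the ELAVL1 antibody brought down beyond the control antibody. The mRNA of ELAVL1 itself was higher in the ELAVL1 RIP, at 10.87 ± 0.18 against 8.91 ± 0.45 (log2 level, SD, n = 3 each), a log2 difference of 1.95 (SE 0.43) and 3.87-fold (limma adjusted p = 0.0420). CD9, a tetraspanin on the surface of pluripotent cells, was 9.45-fold higher (log2 difference 3.24, SE 0.45, adjusted p = 0.0116). Among cell cycle regulators, the kinases CDK6 and WEE1 were higher by 3.23 (SE 0.57) and 2.43 (SE 0.42), although only 1 of the 3 WEE1 probe sets was called. Of 48 cell cycle genes 2 rose and 1, CDC6, fell by 2.99, and 3 rose and 5 fell when adjusted over the list alone. The list's median was −0.62 and it was not called (camera adjusted p = 0.805). The largest rises were those of the zinc finger gene ZNF678 (log2 difference 5.52, SE 0.995), the ubiquitin ligase adaptor KLHL11 (5.24, SE 1.01), RCC2, which acts in mitosis (5.10, SE 1.13), CDCA4 (4.80), KHSRP (4.78), SHQ1, an assembly factor of H/ACA ribonucleoproteins (4.46), CBFA2T2 (4.44) and KLHL14 (4.41). The largest falls were those of the zinc transporter SLC39A13 (−5.76, SE 0.93), the small nucleolar RNA SNORD104 (−5.14, SE 0.55), ZNF648 (−5.10, SE 0.41), SDF2L1 (−4.95), ALDH6A1, an enzyme of valine breakdown (−4.70), the homeobox gene HOXB3 (−4.66), the growth factor NRG1 (−4.54) and CSTL1 (−4.43). For NRG1 only 1 of 2 probe sets pointed this way. The T7 control arrays varied widely for the top rises, with an SD of 1.82 for ZNF678, 1.75 for KLHL11 and 2.65 for RCC2. Leaving out a single T7 control array, the log2 difference of RCC2 was 3.58 without replicate 1, 5.72 without replicate 2 and 6.0 without replicate 3, that of KLHL11 was 4.28 without replicate 1 and 6.0 without replicate 3, and that of ZNF678 was 6.57 without replicate 1. Without T7 control replicate 1 it was 4.03 for KHSRP, 3.83 for SHQ1, −5.06 for SLC39A13, −5.69 for SDF2L1 and −3.71 for NRG1. Of 46 called named genes 44 lost their call without at least 1 array, and ZNF648 and HOXB3 kept theirs without each. CDCA4, KHSRP and KLHL14 were low in the T7 control RIP but not in total RNA, where their log2 levels were 10.47, 10.24 and 10.49.

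The respiratory chain, ribosomal protein and endoplasmic reticulum chaperone lists were called lower in the ELAVL1 RIP than in the T7 control RIP, while glycolysis (camera adjusted p = 0.634) and the list of translation factors and other 5' TOP mRNAs (0.283) were not called. Of 77 measured nuclear-encoded respiratory chain genes 15 fell and 0 rose, 36 fell and 1 rose when adjusted over the list alone, and the median log2 difference was −1.25 against −0.32 over all genes. The camera adjusted p of this list was 2.24e-09, and with an estimated correlation its adjusted p was 0.740. COX5B, a subunit of cytochrome oxidase, fell by 3.27 (SE 0.39), and NDUFB9 of complex I fell by 3.26 (SE 0.46). Of 73 mitochondrial ribosomal protein genes 11 fell, and 21 fell and 1 rose when adjusted over the list alone, with a median of −1.03 (camera adjusted p = 0.000703), and MRPL57 fell by 3.33 and MRPL14 fell by 4.30 (−5.26 without T7 control replicate 1). With an estimated correlation the adjusted p was 0.957. Of 64 cytosolic ribosomal protein genes 5 fell, 14 when adjusted over the list alone, with a median of −0.80 (camera adjusted p = 6.59e-05), and RPS21 fell by 3.85 (SE 0.40). With an estimated correlation the adjusted p was 0.805. RPS15 fell by 2.17, in 1 of its 2 probe sets. Of 21 endoplasmic reticulum chaperone and stress genes 4 fell, 5 when adjusted over the list alone, with a median of −1.18 (camera adjusted p = 0.00453). With an estimated correlation the adjusted p was 0.797. HSP90B1 fell by 2.77 (SE 0.38) and SDF2L1 fell by 4.95. After quantile normalization the camera adjusted p was 0.670 for cytosolic ribosomal proteins, 0.124 for mitochondrial ribosomal proteins and 0.0509 for the chaperones, while the respiratory chain stayed called at 0.00044 with a median of −0.62. Without both arrays named above it was 0.422 and 0.246 for the ribosomal lists and 0.00803 for the respiratory chain, and 0.144 for the mitochondrial ribosomal list without T7 control replicate 1 alone. Other genes as bright in the controls were also low. Random lists matched on the mean control level had a median of −0.858, against −0.991 for the 214 respiratory chain and ribosomal protein genes.

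Of 47 mRNAs reported elsewhere as ELAVL1 targets, 4 rose and 1 fell, and 7 rose and 3 fell when adjusted over the list alone. The 4 were KHSRP, itself a binder of AU-rich elements, EIF4E, the cap-binding translation factor (2.49, SE 0.46), ELAVL1, and the RNA-binding protein TIAL1 (1.91, SE 0.41). The transcription factor JUN, named after its value was seen, fell by 2.58. The list's median was −0.47, below 0 and below the −0.32 of all genes, while camera placed it above other genes without a call (adjusted p = 0.283). Of 32 pluripotency genes only CD9 passed the test, and the list was not called (adjusted p = 0.859). Among markers of other cells, 0 of 27 lineage markers and 0 of 17 blood markers passed in limma's test, which gave 4692 probe sets with an unadjusted p under 0.05, and 1 of 20 fibroblast and feeder markers did. That gene, S100A4, fell by 2.22 (SE 0.51). Their camera adjusted p were 0.815, 0.726 and 0.805. Of 54 histone genes 0 passed, with a median of −1.27 (adjusted p = 0.0703). The histone list was called lower after quantile normalization (adjusted p = 0.00715), after median centring (0.0433) and without both arrays named above (4.69e-12), with the preset correlation in each. On the values as deposited its adjusted p was 0.957 with an estimated correlation. ACTB was higher by 1.61 (adjusted p = 0.0921) and GAPDH differed by −0.11 (adjusted p = 0.961), neither past the threshold, and the sign of GAPDH turned with quantile normalization (0.61) and without T7 control replicate 1 (0.41).

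In total 184 probe sets were higher and 700 lower in the ELAVL1 RIP than in the T7 control RIP, all of them by at least 2-fold, with an unadjusted p under 0.05 for 4692. The groups did not overlap for 24.2% of probe sets, where chance gives 10%. The median over all probe sets was −0.27, and the share of calls that were higher, 20.8%, became 62.2% after quantile normalization (741 higher, 451 lower) and 45.2% after median centring (354 and 430). Without both arrays named above 4267 were higher and 8481 lower. Leaving out T7 control replicate 1 alone gave 800 and 2911. Leaving out T7 control replicate 2 or 3 gave 12 and 24, or 7 and 14. Leaving out ELAVL1 replicate 1, 2 or 3 gave 0 and 2, 0 and 3, or 1 and 9 in limma's test, with 3180, 3156 and 3293 probe sets at an unadjusted p under 0.05. The median SE then rose from 0.526 to 0.631, 0.635 and 0.627, while the median difference over all probe sets moved little (−0.248, −0.264 and −0.294).

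**Figure D2:**
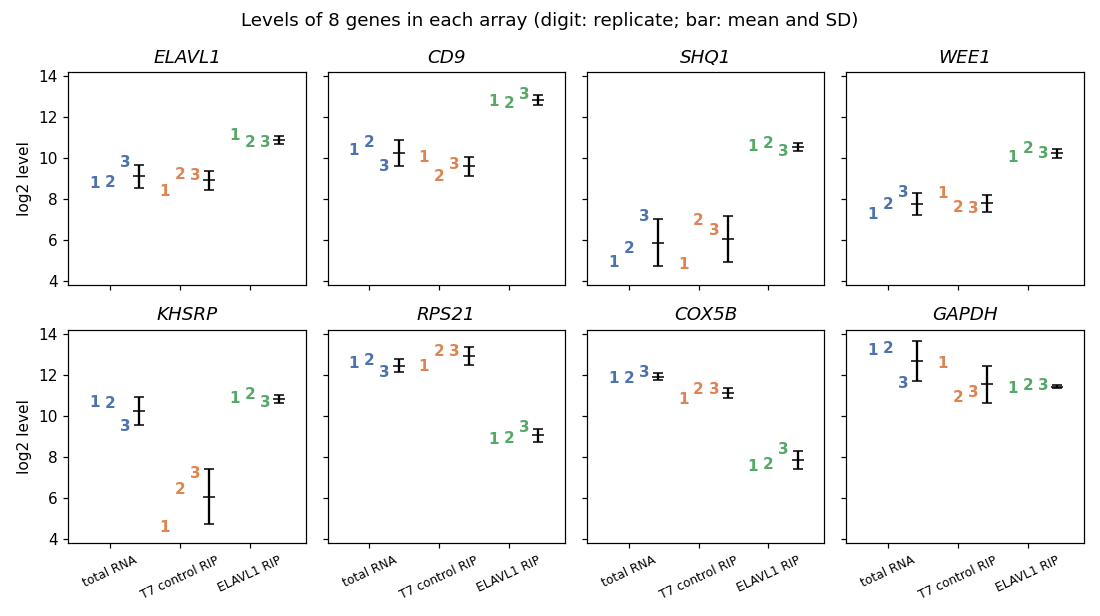
Log2 level of 8 genes on each of the 9 arrays by group, with digits giving the replicate and the black bar the mean and SD of the 3 arrays. ELAVL1, CD9, SHQ1 and WEE1 are highest in the ELAVL1 RIP, RPS21 and COX5B are lowest there, KHSRP is low only in the T7 control RIP, and GAPDH lies at 11.42 ± 0.07 in the ELAVL1 RIP.

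Against total RNA, the comparison that asks what was enriched over the input, ELAVL1 mRNA was again higher in the ELAVL1 RIP, by 1.76 on the log2 scale (SE 0.43, n = 3 each, 3.37-fold, limma adjusted p = 0.0493). CD9 was higher by 2.59 (SE 0.45), CDK6 was higher by 2.39 and WEE1 by 2.46. Of 48 cell cycle genes these 2 rose and 4, among them PCNA and CDC25B, fell, and 3 rose and 11 fell when adjusted over the list alone, with a median of −0.68 and no call (camera adjusted p = 0.704). The largest rises were those of the AAA ATPase FIGNL1 (4.71, SE 0.60), the kinase STK35 (4.67, SE 0.68), SHQ1 (4.65, SE 0.68), the kinase NUAK1 (4.55), CNTD1 (4.54), RPL13AP17 (4.41), the vesicle protein VAMP5 (4.38) and the melatonin receptor gene MTNR1A (4.21). RPL13AP17 is a pseudogene, and its probes could also read related sequences. The largest falls were those of ATP5PF, a subunit of ATP synthase (−5.05, SE 0.64), AKR1E2 (−4.98), ALDH6A1 (−4.83), ZNF648 (−4.81), CYTH3 (−4.76), PPP1R3C, which targets a phosphatase to glycogen (−4.52), the mitochondrial protein CHCHD1 (−4.44) and HOXB3 (−4.41). VAMP5, RPL13AP17 and MTNR1A were also high in the T7 control RIP, at 10.91, 9.74 and 9.58. Without total RNA replicate 3 the log2 difference was 5.28 for SHQ1 and −4.44 for ATP5PF. Each of 47 called named genes lost its call without at least 1 array. The ubiquitin-conjugating enzymes UBE2E2 and UBE2R2 moved in opposite directions, by 4.10 (SE 0.51) and −3.39 (SE 0.43). Of 23 such enzymes 1 rose and 3 fell, 1 and 4 when adjusted over the list alone, and the list was not called (median −0.83, camera adjusted p = 0.782).

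The respiratory chain and ribosomal protein lists had lower medians against total RNA than all genes together. Of 77 respiratory chain genes 36 fell and 0 rose, 59 fell and 2 rose when adjusted over the list alone, and the median was −1.98 against −0.39 over all genes (camera adjusted p = 1.22e-19). With an estimated correlation the adjusted p was 0.394. COX5B fell by 4.06 (SE 0.39) and COX7B fell by 3.43 (SE 0.37). Of 64 cytosolic ribosomal protein genes 21 fell, 46 when adjusted over the list alone, with a median of −1.25 (camera adjusted p = 2.31e-15). RPS21 fell by 3.40 and RPS15 fell by 2.51, and the adjusted p was 0.394 with an estimated correlation. Of 73 mitochondrial ribosomal protein genes 20 fell, and 38 fell and 1 rose when adjusted over the list alone, with a median of −1.72 (camera adjusted p = 6.09e-13). MRPL57 fell by 4.15 and MRPS33 fell by 3.04, and the adjusted p was 0.797 with an estimated correlation. These 3 lists stayed called after quantile normalization, with camera adjusted p of 2.02e-11, 0.00171 and 2.73e-07, but their medians shrank to −1.14, −0.40 and −0.92. On the values as deposited their 214 genes together had a median of −1.65, against −1.03 in random lists matched on the mean control level.

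The other lists called by camera against total RNA passed by narrower margins. Of 18 translation factor and other 5' TOP genes 2 fell, 6 when adjusted over the list alone, with a median of −1.06 (camera adjusted p = 0.0193, and an adjusted p of 0.740 with an estimated correlation). EIF3H fell by 3.05 (SE 0.44) and EIF3L fell by 2.20 (SE 0.40). Of 18 glycolysis genes only GPI fell (2.94 on the log2 scale, SE 0.67, 7.70-fold), 4 did when adjusted over the list alone, and the median was −1.23 (camera adjusted p = 0.0228, and an adjusted p of 0.841 with an estimated correlation). The list of 40 TGF-beta, FGF and WNT signalling genes was placed above other genes with a median of 0.01 (camera adjusted p = 0.0247, and an adjusted p of 0.957 with an estimated correlation). In it the WNT effector TCF7L2 rose by 2.88 (SE 0.60), or 3.55 without total RNA replicate 3, and the growth factor FGF2 fell by 2.15 (SE 0.45), and 3 rose and 2 fell when adjusted over the list alone. The 358 olfactory receptor genes, not expected in these cells, were placed above other genes although their median was −0.13. Of them 0 rose and 1, the pseudogene OR7E19P, fell by 1.72, and 0 passed when adjusted over the list alone (camera adjusted p = 0.0494, and an adjusted p of 0.957 with an estimated correlation). After quantile normalization the camera adjusted p was 0.831 for the 5' TOP list, 0.192 for glycolysis, 0.857 for olfactory receptors and 0.00515 for the signalling list. After median centring it was 0.0548 for the signalling list. Without the dimmest 33.3% of probe sets it was 0.0515 for glycolysis and reached 0.05 for the 5' TOP list. Without both arrays named above it was 0.102 for the 5' TOP list and 0.102 for olfactory receptors, while glycolysis (0.013) and the signalling list (0.0126) stayed called. Without total RNA replicate 3 it was 0.0877 for the 5' TOP list and 0.110 for olfactory receptors. Without ELAVL1 replicate 3 it was 0.0666 for olfactory receptors, and without ELAVL1 replicate 1 it was 0.0585 for the signalling list. Of the 47 reported targets ELAVL1 rose and the cyclin CCNB1 fell by 1.90 (SE 0.38), with 0 and 1 when adjusted over the list alone, and the list was not called (median −0.13, camera direction above other genes, adjusted p = 0.0703). It was called higher after quantile normalization (median 0.46, adjusted p = 0.00578) and without both arrays (median 0.06, adjusted p = 0.00121), with the preset correlation. On the values as deposited its adjusted p was 0.957 with an estimated correlation. ACTB and GAPDH differed by 1.14 (adjusted p = 0.212) and −1.25 (adjusted p = 0.316).

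**Figure D3:**
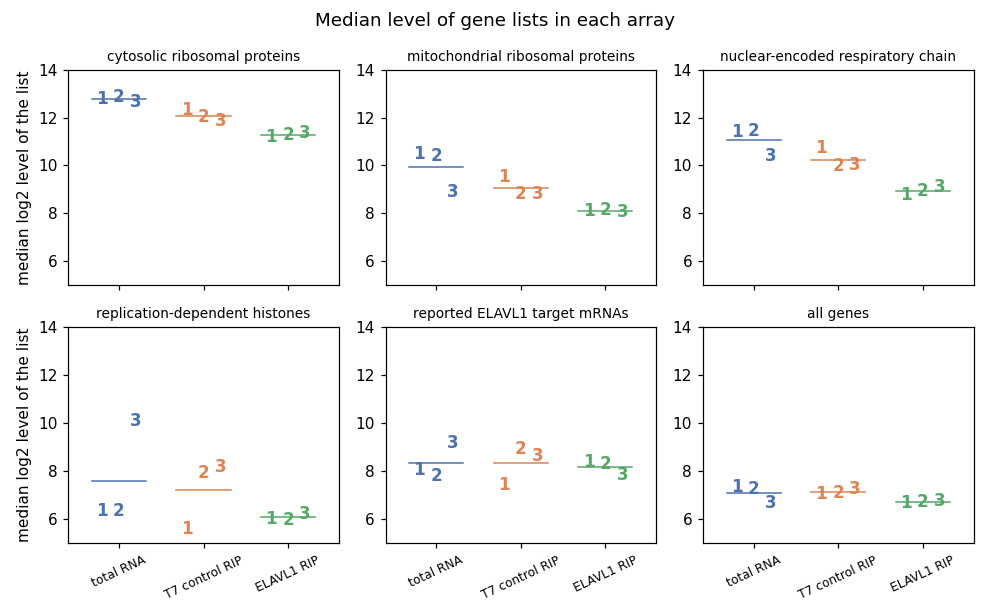
Median log2 level of 5 gene lists and of all genes on each array, with digits giving the replicate and lines the mean of the 3 array medians of a group. The medians of the cytosolic ribosomal, mitochondrial ribosomal and respiratory chain lists are lowest in the ELAVL1 RIP, and the histone median is 10.10 on total RNA replicate 3 against 6.32 on replicates 1 and 2.

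In total 156 probe sets were higher and 1148 lower in the ELAVL1 RIP than in total RNA, all by at least 2-fold, with an unadjusted p under 0.05 for 4986. The groups did not overlap for 26.2% of probe sets, where chance gives 10%. The median over all probe sets was −0.31, and the share of calls that were higher, 12%, became 53.5% after quantile normalization (455 and 396) and 22.7% after median centring (238 and 812). Without both arrays named above 2775 were higher and 10997 lower, and without total RNA replicate 3 alone 532 and 3501. Leaving out total RNA replicate 1 or 2 gave 35 and 210, or 24 and 123. Leaving out ELAVL1 replicate 1, 2 or 3 gave 7 and 26, 0 and 0, or 12 and 93, and without replicate 2 limma still gave 3463 probe sets at an unadjusted p under 0.05. The median SE again rose from 0.526 to 0.631, 0.635 and 0.627, with median differences of −0.302, −0.311 and −0.338.

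The 2 controls were compared to show what the control antibody brought down relative to input. VAMP5 (log2 difference 4.85, SE 0.48) and RPL13AP17 (4.82, SE 0.40) were higher in the T7 control RIP, as were the potassium channel gene KCNMA1 (4.65, SE 0.81), ROGDI (4.26), MTNR1A (4.25), CSTL1 (4.20), TMEM151B (4.08) and ANGPTL8, a regulator of lipoprotein lipase (4.06). The Notch coactivator MAML3 (−5.16, SE 0.73), KLHL14 (−4.89, SE 0.42), CAPN6 (−4.72), the pseudogene RPL36AP40 (−4.61), the calcium sensor STIM2 (−4.56), CDCA4 (−4.53), the ephrin receptor EPHA6 (−4.40) and AKR1E2 (−4.34) were lower. Without T7 control replicate 1 the log2 difference was −4.16 for MAML3, −3.47 for STIM2, −3.73 for AKR1E2 and −3.44 for KHSRP, and 3.81 for KCNMA1. For STIM2 it was −5.24 without T7 control replicate 2 and for CAPN6 −5.35 without T7 control replicate 3, and without total RNA replicate 3 it was 3.45 for ROGDI, 3.85 for KCNMA1 and −5.40 for CDCA4. Of 23 called named genes 16 lost their call without at least 1 array. Each of those fits kept the ELAVL1 arrays, which correlate closely and enter the shared estimate of the spread. A limma fit to the 6 control arrays alone called 0 probe sets, so no call here rests on the compared arrays alone. KHSRP was lower by 4.19 on the log2 scale (SE 0.65, limma adjusted p = 0.0272) and the olfactory receptor gene OR8I2 by 3.72. ELAVL1 differed by −0.20 (SE 0.43, adjusted p = 0.997), and its sign turned without total RNA replicate 3 (0.13), without T7 control replicate 1 (0.06) and without both (0.39).

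The respiratory chain and ribosomal protein lists were called lower in the T7 control RIP than in total RNA too, with few single genes passing. Of 77 respiratory chain genes 0 fell and 1, labelled SDHC, rose by 2.89 (SE 0.45), while 7 fell and 2 rose when adjusted over the list alone, and the median was −0.76 (camera adjusted p = 2.34e-07, and an adjusted p of 0.761 with an estimated correlation). The authors' deposited table places this SDHC probe set on chromosome 17, while the gene lies on chromosome 1, so it could read a related sequence, and the SDHC probe set on chromosome 1 differed by 0.84 (adjusted p = 0.942). Of 64 cytosolic ribosomal protein genes 0 passed, and 0 when adjusted over the list alone, with a median of −0.63 (camera adjusted p = 4.61e-07, and an adjusted p of 0.761 with an estimated correlation). Of 73 mitochondrial ribosomal protein genes MRPS33 fell by 2.36 (SE 0.38), 8 fell when adjusted over the list alone, and the median was −0.78 (camera adjusted p = 9.47e-06, and an adjusted p of 0.957 with an estimated correlation). The 54 histone genes had a median of −0.40 and were not called (adjusted p = 0.859). Without both arrays named above their median was 1.54, and 1.99 above that of all genes, with a camera adjusted p of 2.13e-11 at the preset correlation. Without total RNA replicate 3 alone it was 1.14 above that of all genes and called (camera adjusted p = 4.84e-07). Without T7 control replicate 1 alone it was 0.33 above and not called (camera adjusted p = 0.0979). With all arrays the adjusted p was 0.964 with an estimated correlation. In total 50 probe sets were higher and 77 lower in limma's test, all by at least 2-fold, and 2599 had an unadjusted p under 0.05. The groups did not overlap for 7.90% of probe sets, where chance gives 10%. Without both arrays 5173 were higher and 9697 lower, without total RNA replicate 3 alone 216 and 705, and without T7 control replicate 1 alone 691 and 670. Leaving out total RNA replicate 1 or 2 gave 9 and 10, or 7 and 9, and leaving out T7 control replicate 2 or 3 gave 16 and 22, or 12 and 30. A limma fit to these 6 arrays alone gave 0 and 0, with 1499 at an unadjusted p under 0.05.

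RNAs that differed from both controls in one direction were listed last. SHQ1 led those higher, at 10.53 in the ELAVL1 RIP, 6.07 in the T7 control RIP and 5.89 in total RNA (mean log2 levels, n = 3). FIGNL1, STK35, METTL4, PFKFB3, ST6GALNAC2, VCPKMT, MAT2B, CD9, WEE1, CDK6, the checkpoint kinase CHEK2 and ELAVL1 were also among them. Those lower were led by ZNF648, ALDH6A1 and HOXB3. There were 36 probe sets higher than both controls and 440 lower, and 0 called in opposite directions. Independent lists of these sizes would share 0.994 and 27.8, but both comparisons use the same ELAVL1 arrays. In 20 simulations of unchanged groups, which made 0.15 calls or fewer on average and shared 0, the strongest probe sets taken in lists of the observed sizes shared 30.6 higher (at most 39) and 216 lower (at most 229), a reference chosen after the result was seen. The 36 higher are within that reference and the 440 lower are above it, but the simulated arrays differ from the real ones. They were drawn independently, with the same spread in each group. In the data the ELAVL1 arrays correlated at 0.944 to 0.963 and the T7 control arrays at 0.516 to 0.960. Total RNA replicate 3 also correlated with T7 control replicates 2 and 3 at 0.835 and 0.820. The reference therefore cannot decide what the shared arrays give without a true difference. Quantile normalization gave 220 and 172, median centring 76 and 252, and leaving out both arrays named above 795 and 4868. Leaving out a single array gave from 0 to 186 higher, the lowest without T7 control replicate 3 and the highest without T7 control replicate 1, and from 0 to 1262 lower, the lowest without ELAVL1 replicate 2.

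The authors' deposited table of regions attached to ELAVL1 replicate 1 holds 2874 regions with a value of at least 2 and up to 26.9 and a median of 2.45. In that list 2160 have a q-value under 0.05. CD9 (chromosome 12, 6308874 to 6347427, build hg19) has a value of 23.7 in the authors' deposited table and UQCRBP1 (chromosome X, 56763676 to 56764010) 22.5. ZNF678 (chromosome 1, 227848940 to 227850161) has 18.4 in the authors' deposited table, the transcription factor gene SOX4 (chromosome 6, 21593001 to 21598850) 17.3 and ELAVL1 (chromosome 19, 8023458 to 8509925) 16.3. The log2 differences against the T7 control RIP and total RNA were 3.24 and 2.59 for CD9, 1.02 and 1.10 for UQCRBP1, and 1.95 and 1.76 for ELAVL1. For these genes the deposited value is therefore larger than the ratio of the group means and cannot be that ratio. The SOX4 probe set of this region was not called on the arrays, with log2 differences of 1.22 against the T7 control RIP (limma adjusted p = 0.387) and 1.31 against total RNA (0.32). The ZNF678 probe set of this region was not called against total RNA (3.31, adjusted p = 0.0995), which does not speak for other probe sets of that gene. The ELAVL1 region also contains, in the authors' deposited tables, the regions of FBN3 (8130288 to 8214730) and RAB11B (8455230 to 8469309), so it does not mark the ELAVL1 gene alone. Exon and UTR annotation of this build was not used here. Of the probe sets on the list 72.9% were higher in the ELAVL1 RIP than in the T7 control RIP and 72.7% higher than in total RNA by their group means, against 34.1% and 30.8% of all probe sets. It held 79 of 183 called higher against the T7 control RIP (43.2%) and 66 of 156 against total RNA (42.3%), while it holds 9.95% of all probe sets, leaving out a few that are not reported here. The list is the authors' own call on these arrays and so is not independent of them. It held 0 of 64 cytosolic ribosomal, 0 of 73 mitochondrial ribosomal and 1 of 77 respiratory chain genes, and 11 of 47 reported targets (23.4%). The share was 27.5% for TGF-beta, FGF and WNT signalling genes (11 of 40), 16.5% for ZNF genes (79 of 479) and 9.09% for immediate early and AU-rich element mRNAs (3 of 33) in the authors' deposited table, so a high share was not particular to reported targets. The authors' deposited list attached to T7 control replicate 1 held 14 of the 64 cytosolic ribosomal genes (21.9%), against 79.2% of all probe sets. It held 67 of the 73 mitochondrial ribosomal and 48 of the 77 respiratory chain genes. Most cytosolic ribosomal genes were thus in neither list, so their absence from the ELAVL1 list does not show that they were not enriched.

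The list attached to T7 control replicate 1 has 22855 regions in the authors' deposited table, all with a q-value under 0.05 and signals from 32.0 to 4440. For all 22834 whose probe set is in the value table, the log2 of the signal equalled the mean log2 level of the total RNA arrays to within 0.001. The signal is thus their geometric mean, and the list holds levels of total RNA, not of the T7 control RIP. The chaperonin gene HSPD1 (chromosome 2, 198351309 to 198364998) has the top signal in the authors' deposited table. The list attached to total RNA replicate 1 has 147 regions with a value of at least 2 and up to 7.13, of which 2 have a q-value under 0.05. Of its probe sets 79.6% were higher in the T7 control RIP than in total RNA, against 45.2% of all probe sets. By these values the lists attached to the total RNA and T7 control arrays look exchanged, which the sources used here do not settle. Of the 2874 regions attached to the ELAVL1 array, 2676 (93.1%) overlapped the 22855 by position, and 17 overlapped the 147. By probe set, 2568 of the 2874 were also among the 22855, which hold 79.2% of all probe sets. Of the 147 regions 134 overlapped the 22855.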

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

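Leaving out both arrays that stand apart, and median centring of single genes, were chosen after the result was seen, as were the gene lists printed by name. Where counts below moved, the cause was not tested unless fewer probe sets or arrays were used. Pairs are higher and lower, in the order ELAVL1 RIP against T7 control RIP, ELAVL1 RIP against total RNA, T7 control RIP against total RNA, and both controls. The counts as reported were 184 and 700, 156 and 1148, 50 and 77, and 36 and 440. Quantile normalization gave 741 and 451, 455 and 396, 64 and 72, and 220 and 172. Median centring gave 354 and 430, 238 and 812, 80 and 158, and 76 and 252. A variance trend with robust estimation gave 96 and 454, 105 and 864, 27 and 48, and 15 and 279. The replicate number as a block gave 86 and 352, 116 and 832, 14 and 21, and 19 and 221. Same-numbered arrays did not consistently deviate together (correlations −0.14, 0.10 and −0.17 against the T7 control RIP, −0.05, −0.10 and −0.12 against total RNA, 0.48, −0.42 and 0.43 between the controls). Between the controls replicates 1 and 3 did so and replicate 2 went the other way, and 3 of 9 arrays lay closest to their own number. Only probe sets with 1 symbol gave 751 lower against total RNA, and 30 and 44 between the controls. The log2(2^value + 16) scale gave 130 lower between the controls. Only the 6 arrays of a comparison gave 388 and 1985 against total RNA, and 0 and 0 between the controls (limma, 1499 at an unadjusted p under 0.05). Without both arrays the counts were 4267 and 8481, 2775 and 10997, 5173 and 9697, and 795 and 4868.

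Leaving out each array gave 0 to 800 higher (lowest without ELAVL1 replicate 1, highest without T7 control replicate 1) and 2 to 2911 lower (the same arrays) against the T7 control RIP. Against total RNA it gave 0 to 532 and 0 to 3501 (ELAVL1 replicate 2, total RNA replicate 3), between the controls 7 to 691 (total RNA replicate 2, T7 control replicate 1) and 9 to 705 (total RNA replicates 2 and 3), and for both controls 0 to 186 (T7 control replicates 3 and 1) and 0 to 1262 (ELAVL1 replicate 2, T7 control replicate 1). The 0 counts are limma's, with 3180 and 3463 probe sets at an unadjusted p under 0.05 against the T7 control RIP (without ELAVL1 replicate 1) and total RNA (without ELAVL1 replicate 2). Of 116 calls of named genes, 99 held with quantile normalization, 109 with median centring, 101 with the mean over a gene's probe sets, 115 without the dimmest 33.3%, 89 with the block, 99 with the variance trend and 116 without both arrays, and 0 turned. Of 93 that use ELAVL1 arrays, 14, 3 and 29 held without replicates 1, 2 and 3. The leading genes were picked as called with groups that did not overlap, so leaving out arrays could not turn their sign. Without both arrays the median SE against the T7 control RIP fell from 0.526 to 0.315, so the calls kept there are weak evidence of stability.

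Lists called numbered 4, 7 and 3, and 0 in each comparison with an estimated correlation. Median centring gave 7 against the T7 control RIP, leaving out both arrays gave 11 between the controls, and leaving out each array gave 4 to 7 (highest without ELAVL1 replicate 3), 7 to 11 (ELAVL1 replicate 3) and 3 to 11 (total RNA replicate 3). None of the 14 calls turned direction in any setting, while 38 of the 61 list tests not called did in at least 1. Relative to all genes, the median of reported targets against the T7 control RIP stood at −0.15 with all arrays and at −0.41 without both arrays. Only camera's direction turned there, from above to below other genes, without a call. Pluripotency genes stood at 0.11 with quantile normalization and from −0.43 to 0.10 without single arrays (T7 control replicates 1 and 2). Without T7 control replicate 3 or 1, lineage markers stood at −0.22 and 0.42, fibroblast markers at −0.026 and 0.40, and blood markers at 0.14 and 0.58. Histones between the controls stood at −0.30 with median centring, −0.29 without the dimmest 33.3%, 1.99 without both arrays, and from −1.03 to 1.14 without total RNA replicates 1 and 3. Camera placed them above other genes with median centring and without the dimmest 33.3%, against their medians, without a call. GAPDH against the T7 control RIP became 0.61 with quantile normalization, 0.19 with median centring, which shifts every gene alike, and 0.41 without both arrays, and ranged from −0.44 to 0.41 without T7 control replicates 2 and 1. ELAVL1 between the controls became 0.39 without both arrays and ranged from −0.37 to 0.13 without total RNA replicates 1 and 3. With the upper 50% of each region list by score, 895 regions of the ELAVL1 list overlapped the list attached to T7 control replicate 1, 2 overlapped the list attached to total RNA replicate 1, and 47 regions of the latter overlapped the former, fewer because fewer regions were used. An overlap of 50% of the shorter region gave 2672, 17 and 134, and the second version 2676, 17 and 134. The 3' UTR analysis was not run. No setting changes how many arrays limit the precision, and 2-fold changes were rarely within reach, as the smallest simulated change, 2 on the log2 scale, was recovered for at most 13 of 100 probe sets.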

Other observations

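The tests of an exchange of arrays, of stem cell markers, of a loss common to both immunoprecipitations and of reported targets were chosen after the result was seen, as was the count of genes beyond all control arrays.

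A view that needs no model counts genes whose 3 ELAVL1 arrays all lie beyond all 6 control arrays. SHQ1 had the widest gap above, 3.19 on the log2 scale, and others among the 15 widest were RCC2 (2.67), the sialyltransferase ST6GALNAC2 (2.6), FIGNL1 (2.57), STK35 (2.41), ZNF678 (2.11), VCPKMT (2.10), the ubiquitin ligase PELI2 (1.86), CD9 (1.86), PFKFB3, which controls glycolytic flux (1.82), and WEE1 (1.73). Among the 15 widest below all controls were ZNF648 (4.10), ALDH6A1 (3.85), HOXB3 (3.84), SNORD104 (3.43), the kinase BRSK2 (2.98), CHMP2A of the ESCRT machinery (2.91), GTF3C6 (2.83), ATP5PF (2.74), RPS21 (2.70) and CHCHD1 (2.65). In all 598 of 28869 probe sets lay above and 3074 below, where chance gives 343.7 each. Median centring turned this to 1352 and 2021, and quantile normalization to 2079 and 1732. Of 64 cytosolic ribosomal protein genes 41 lay below all controls (64.1%), of 77 respiratory chain genes 47 (61.0%) and of 73 mitochondrial ribosomal protein genes 26 (35.6%), against 11.2% of all genes. After median centring the counts were 26, 39 and 23. On the values as deposited, Fisher's exact test over genes, adjusted over 50 tests, gave 2.27e-22, 5.30e-24 and 6.48e-07, and it treats genes as independent, which they are not. The 11.2% of all genes was not matched on the level in the controls.

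Total RNA replicate 3 and T7 control replicate 1 resembled arrays of the other control group more than their own. An exchange of the 2 arrays needs each to match the arrays it would join, and the highest such correlation was 0.835, below the 0.944 of the loosest ELAVL1 pair, which argues against a plain exchange. A different yield of RNA without a poly(A) tail, such as histone and small nucleolar RNA, would leave the other genes alike, yet without those genes total RNA replicate 3 correlated with replicates 1 and 2 at no more than 0.587. A different share of stem cells could account for part of it, since 58.8% of 17 stem cell markers were higher in total RNA replicate 3 than in replicates 1 and 2 (26.4% of all genes) and 70.6% were lower in T7 control replicate 1 than in replicates 2 and 3 (42.2% of all genes), but neither share reaches the 75% set for it, and the cells behind each array cannot be told apart here. The median of those markers was 7.38, 7.5 and 9.29 in total RNA, 7.54, 10.28 and 10.64 in the T7 control RIP and 8.73, 9.10 and 8.94 in the ELAVL1 RIP, while the medians of liver, erythroleukaemia, B lymphoblastoid and epithelial markers were all lower on total RNA replicate 3 than on replicates 1 and 2, as was that of all genes (7.35, 7.26 and 6.65), and all 4 were higher on T7 control replicate 1 than on replicates 2 and 3 (epithelial 8.32, 6.56 and 7.26, erythroleukaemia 7.17, 6.38 and 6.44), where that of all genes was lower (7.03, 7.09 and 7.25).

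The 214 ribosomal protein and respiratory chain genes had a median log2 difference of −0.991 against the T7 control RIP and −1.65 against total RNA. The medians over all genes were −0.32 and −0.39. Against the T7 control RIP 15 of 77 respiratory chain, 5 of 64 cytosolic ribosomal and 11 of 73 mitochondrial ribosomal genes were called lower. Against total RNA 36, 21 and 20 were, and 0 were called higher in either comparison. Compression of bright signals was tested with 10000 random lists matched on the mean over all 6 control arrays. Their genes were not matched on the level in either control alone. The lists were lower in the T7 control RIP than in total RNA, with medians from −0.63 to −0.78 against −0.10 over all genes. Against total RNA none of the matched lists lay as low, their median was −1.03 and their 2.5 percentile was −1.22. Because of the pooled match this does not exclude compression. Random lists also treat genes as independent, and no list was called with an estimated correlation. Against the T7 control RIP such compression is likewise a candidate explanation, because 7.91% of matched lists lay as low and their median was −0.858. Scaling between arrays was left open there, against the rule written beforehand, which it failed narrowly: quantile normalization moved the 3 lists from −0.674 to −0.306 relative to all genes, past the −0.299 of the most extreme random list, but it also took the cytosolic ribosomal median from −0.80 (quartiles −1.15 and −0.30) to −0.10 (−0.49 and 0.37) with an adjusted p of 0.670, and the mitochondrial ribosomal median from −1.03 to −0.36 with 0.124, whereas the respiratory chain stayed called (−1.25 to −0.62, adjusted p = 0.00044), so this scaling did not end that list's call. A loss common to both immunoprecipitations would give no such difference, and −0.674 lies below the −0.132 of random lists, but compression and scaling leave it open, as they do a true lack of binding.

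Of 47 reported ELAVL1 targets 5 lay above all controls (10.6%, against 2.32% of all genes) and 5 below (10.6%, against 11.2%), while of 33 immediate early and AU-rich element mRNAs 0 lay above and 5 below. After median centring the counts above and below were 6 and 1 for the targets, and 1 and 2 for the others. The unadjusted Fisher's exact p for targets above was 0.00451, and 0.0563 after adjustment over 50 tests, so the hypothesis was not settled.

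For each comparison there are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split was the only 1 of 10 to reach its count against the T7 control RIP (884 calls, highest other 0) and against total RNA (1304 calls, highest other 0). Between the controls 2 of 10 splits reached the real count of 127, and the other called 11320, with total RNA replicates 1 and 2 and T7 control replicate 1 on one side, which points to a structure of the samples that the labels do not give.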
